A study of Homo sapiens with 8 samples.

How the data were processed

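Poly(A) RNA of RPE-1 cells was sequenced in 8 libraries, 1 for each combination of time (1 h or 6 h), atRAL (0 or 25 µM) and EV (0 or 2000000000 particles per ml). The RNA was extracted with TRIzol and the libraries were made with a stranded TruSeq mRNA kit, per the labels' protocols. Groups were taken from the sample titles and treatment labels.

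The values came from 1 table of 46427 genes. Its read counts per gene were deposited by the authors as whole numbers, without normalisation, per the file headers. The same table holds FPKM (fragment counts scaled to transcript length and library size), which the authors computed before deposition, per the file headers. A further 8 per-sample columns, holding TPM (length-scaled values brought to a common total), were not used. HISAT2 2.1.0, StringTie 2.1.3b and the genome GRCh38 are named, without their roles, per the submitters' processing notes. The counter, the annotation release, filters and the strand setting are not given in the sources used here. Among the gene values of the counts, the value 2 (7137 times) is commoner than 1 (6177), 3 (5479) or 4 (4728), so a count need not be a single independent read. Identifiers of 44698 genes matched the reference table of GRCh38 patch 14, which gave coordinates and gene types, and 20670 genes had no count in any library.

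Total counts per library ran from 45566237 (atRAL at 1 h) to 71822269 (EV at 6 h). A floor of 3 counts corresponds to 0.042 to 0.066 CPM. The 10 most abundant genes held 8.81% to 10.32% of the counts, and FN1, the fibronectin gene, 3.2% to 3.49%. Under 4 ways of scaling (TMM, relative log expression, upper quartile and none) the median log2 change of all genes lay closest to 0 with TMM at EV 1 h (-0.001) and farthest with the upper quartile at atRAL 6 h (-0.058).

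The comparisons, models, thresholds, gene lists and most alternatives were chosen before the data were examined. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and the 4 combinations of time and atRAL as groups. That kept 17044 genes and left out 29383. Counts were scaled by TMM and tested by edgeR's quasi-likelihood F test (robust) in R 4.3.3 with edgeR 4.0.16. P-values were adjusted over all 17044 genes by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. SE is the standard error of a log2 fold change.

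No condition has a replicate, and 3 models used the repeats inside the layout. Model A has time, atRAL within time and EV within time (6 coefficients, 2 residual degrees of freedom). It gave the effects of atRAL and of EV at each time, 2 libraries against 2, and their differences between the times. Model B has the 4 combinations of time and atRAL and EV within atRAL status (2 residual degrees of freedom). It gave the effect of EV with atRAL, without atRAL, their difference, and the change with time without atRAL. Model C has the same 4 combinations and 1 EV effect (3 residual degrees of freedom). The biological coefficient of variation was 9.66% in model A, 13.9% in B and 12.5% in C. Model A takes the interaction of atRAL and EV within a time as spread, and model B takes the difference of the EV effect between the times as spread. All tests were two-sided.

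Pairs of single libraries were compared as log2 ratios of TMM-scaled CPM with a prior count of 2, for genes with at least 100 counts in one of the pair and a ratio of at least 2-fold. The response to atRAL with EV was compared with that without EV over the genes called for atRAL at 6 h, with 2000 bootstrap draws over genes for 95% intervals. Shares of variance came from the 7 orthogonal contrasts of the layout, and k-means used 2000 genes, 4 clusters and 50 starts.

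The 33 gene lists were written from general knowledge. In them 14 symbols were matched by synonym and 1 was not matched. The 32 lists with at least 5 measured members were tested by camera in limma 3.58.1 with a preset correlation of 0.01, by camera with an estimated correlation, and by fry. Their p-values were adjusted over the 32 lists. For single pairs and responses, the median of a list was placed among 10000 random lists matched on mean expression in 20 bins. Such random lists lack the co-regulation that members of a gene list can share, so the percentile is a rank and not a chance rate. Counts called adjusted over the list alone repeat the adjustment within the list.

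The genes named follow a rule. For a tested effect they are the 10 highest and the 10 lowest log2 fold changes among called genes. These had an average log2 CPM of at least 1, a gene symbol that is not a clone name or pseudogene, and at least 1.5-fold change in the same direction in each pair. For a pair of libraries they are the 6 highest and 6 lowest ratios, and for a list up to 4 members with the largest change. Genes named outside the rule are said to be chosen after their values were seen. Readthrough models, which span 2 neighbouring genes, and near-identical copies are called uncertain, since reads can be assigned to either.

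The models were tested on simulated data with 200 changed genes among 17044, at fold changes of 1.5, 2 and 4 and with the dispersions of the data. The changed genes were drawn from those with an average log2 CPM above 1, and each change was equal in all treated libraries of the tested effect. The other genes were simulated without any effect of time, atRAL or EV. The alternatives were RLE scaling, no filter, a minimum count of 50, DESeq2 1.42.0, limma-voom, limma-trend on log2 FPKM with pseudocounts 1 and 0.1, no EV term, the 4 libraries of a time alone, and each library left out in turn. For the other results they were prior counts of 0.5 and 4, a minimum of 20 counts, 3 and 6 clusters, and 1000 genes. Leaving out mitochondrial mRNAs and ribosomal RNA genes, leaving out readthrough genes, and the difference of the EV effect between the times were added after the data were examined. Further calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.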

Results

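The series holds 8 RNA-seq libraries of RPE-1, a line of human retinal pigment epithelial cells immortalised with telomerase, taken 1 h or 6 h after treatment. All-trans-retinal (atRAL), the retinaldehyde released from light-exposed visual pigment, was added at 25 µM. Extracellular vesicles (EV), membrane particles shed by cells, came here from mesenchymal stem cells of the tonsil and were added at 2000000000 particles per ml. Each of the 2 times has a control, EV alone, atRAL alone and atRAL plus EV, with 2500000 cells treated and 1 library per condition.

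At 1 h the libraries held 56145424 (control), 58890623 (EV), 45566237 (atRAL) and 70916624 (atRAL plus EV) counts. At 6 h they held 71223316, 71822269, 62093395 and 63051076 counts in the same order. No condition was repeated, and an effect was tested where the layout repeats it. The effect of atRAL at 6 h, for example, sets the 2 libraries with atRAL against the 2 without, allowing for EV. The labels name no separate cultures, and with 1 library per condition the p-values measure only the spread between these libraries. Differences between single libraries have no replicate check and are given as higher or lower with no p-value. Floors cover counting error only, and bootstrap intervals cover the spread over genes only, not that between cultures.

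The first question is what atRAL does to the cells. After 6 h with atRAL, CHAC1, whose product degrades glutathione, rose 71.8-fold (log2 fold change 6.17 ± 0.13 SE, adjusted p = 1.3e-06, edgeR, 2 libraries against 2). It stood at 1.29 counts-per-million (CPM) in the control and at 85 CPM with atRAL alone. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose 25.8-fold (4.69 ± 0.3, adjusted p = 0.0017). CXCL8, which encodes the chemokine interleukin 8, rose 22.1-fold (4.47 ± 0.23, adjusted p = 0.00038). BMP4, which encodes a secreted bone morphogenetic protein, fell by 3.9 ± 0.49 on the log2 scale (adjusted p = 0.016), from 48.6 CPM in the control to 1.76 with atRAL alone. The BMP4 call was lost without any 1 of the 4 libraries of 1 h (control, EV, atRAL, or atRAL plus EV), with adjusted p from 1.7e-09 to 0.057 over the 8 fits that each left out a library. Of 17044 genes tested, 2718 rose and 2422 fell, 676 and 426 of them by at least 2-fold. The majority turned on the deposited FPKM, with 2110 higher and 2473 lower on log2(FPKM + 1) and 2129 and 2605 on log2(FPKM + 0.1).

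Genes of the integrated stress response, the programme driven by the transcription factor ATF4, formed the list with the highest median. Of 22 measured members 21 rose and 0 fell, and 21 rose when adjusted over the list alone. The median log2 change was 2.43 (camera adjusted p = 1.4e-20, adjusted p = 0.59 with an estimated correlation). ATF3 rose by 6.77 ± 0.61 (adjusted p = 0.0088), TRIB3 by 4.7 ± 0.22 (adjusted p = 2e-04), SESN2 by 4.29 ± 0.11 (adjusted p = 1.8e-06) and DDIT4 by 4.27 ± 0.18 (adjusted p = 9.8e-05). CTH, which makes cysteine from cystathionine and lay outside the list, rose by 5.6 ± 0.15 (adjusted p = 2.1e-06). INHBE, which encodes an inhibin beta subunit, had 0 counts in the control and 985 with atRAL alone, at least 377-fold higher by a floor of 3 counts in the control library. With EV it had 4 counts, and 352 with atRAL plus EV (adjusted p = 0.0058 over both pairs).

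**Figure D1:**
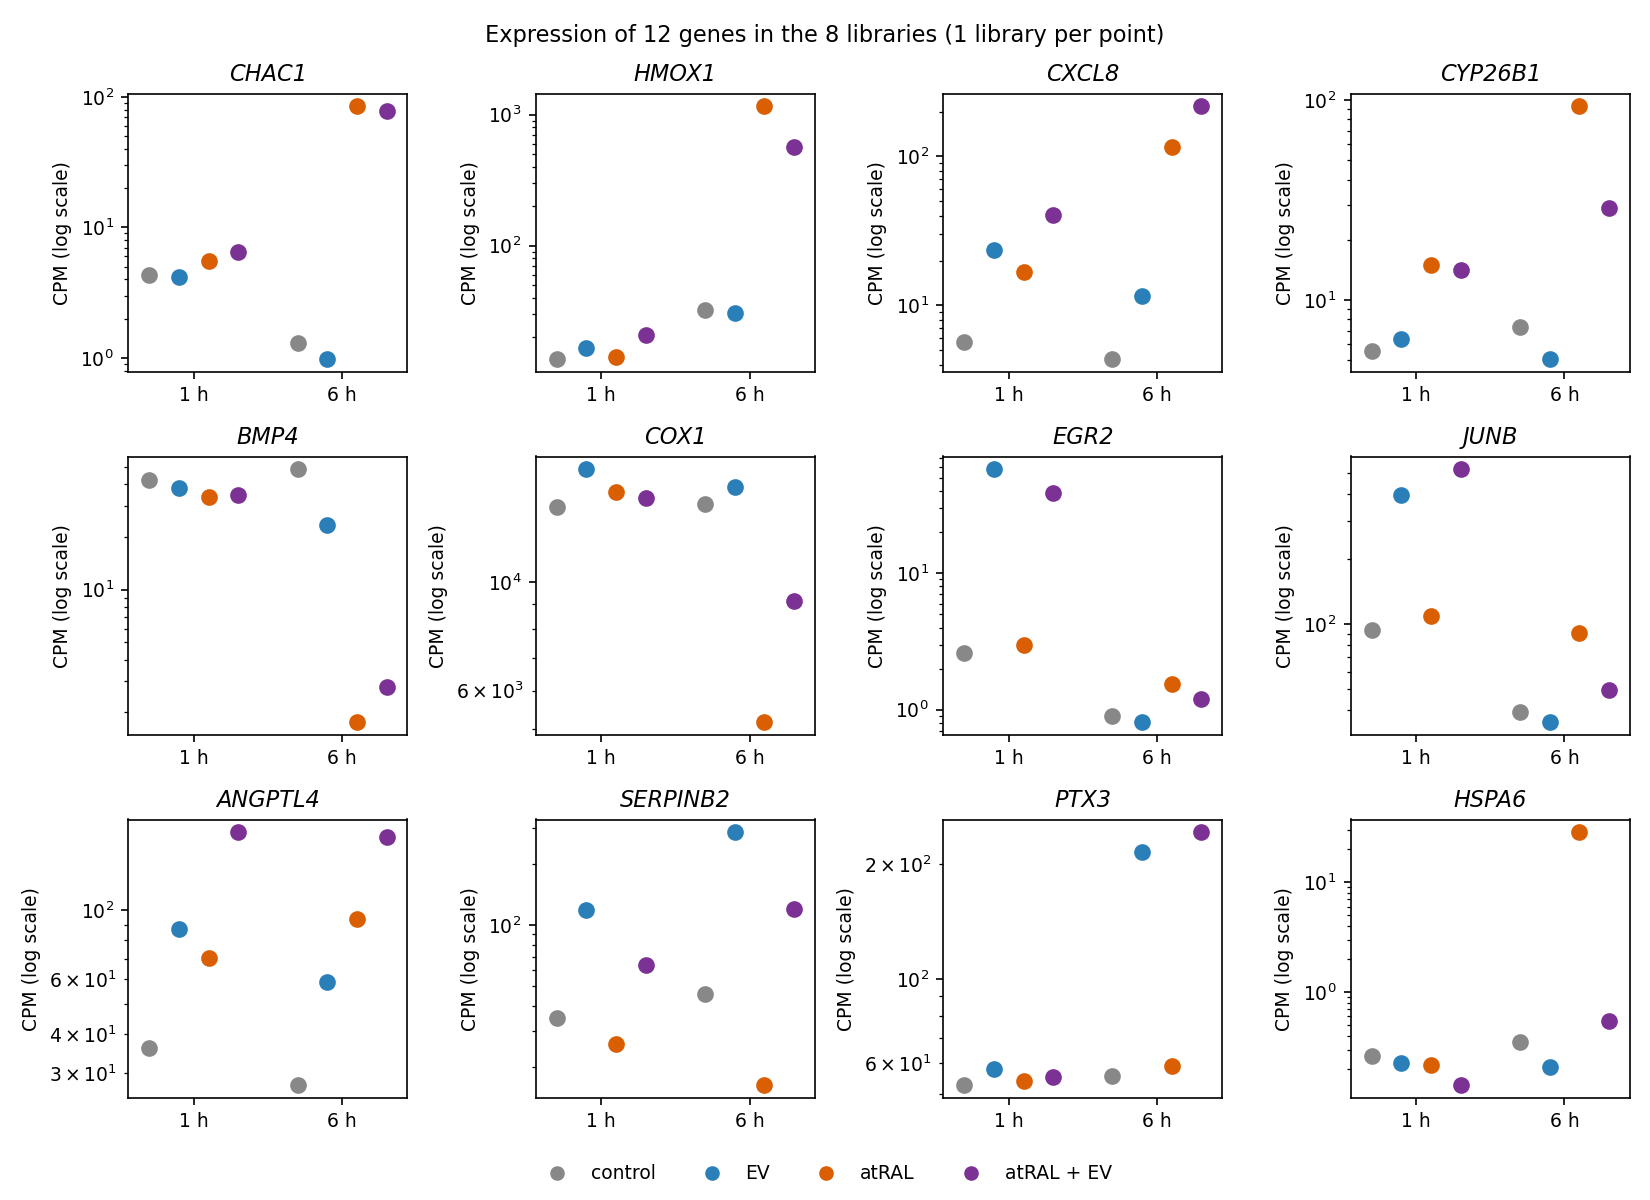
CPM on a log axis for 12 genes in each of the 8 libraries, 1 point per library, grouped by time and coloured by treatment. CHAC1 stood at 85 and 77.9 CPM in the libraries with atRAL at 6 h against 1.29 and 0.98 without, and EGR2 at 58 and 38.5 CPM in the libraries with EV at 1 h against 2.59 and 3 without.

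Targets of NRF2, the transcription factor of the antioxidant response, rose as a group. Of 24 members 18 rose and 0 fell, and 19 rose when adjusted over the list alone (median 0.69, camera adjusted p = 1.8e-09, adjusted p = 0.59 with an estimated correlation). Besides HMOX1, the cystine transporter gene SLC7A11 rose by 3.02 ± 0.1 (adjusted p = 1e-05) and OSGIN1 by 2.35 ± 0.4 (adjusted p = 0.025). GCLM, which encodes a subunit of the enzyme of glutathione synthesis, rose by 1.81 ± 0.1 (adjusted p = 4.5e-05). Of 24 autophagy and lysosome genes 13 rose and 0 fell, with 13 adjusted over the list alone (median 0.29, camera adjusted p = 3.7e-06, adjusted p = 0.59 with an estimated correlation). Among them GABARAPL1 rose by 2.56, the cargo receptor gene SQSTM1 by 2.24, MAP1LC3B by 1.8 and WIPI1 by 1.21.

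Inflammatory genes rose with atRAL as well. Of 21 measured members of the NF-kB and cytokine list 12 rose and 0 fell, and 13 rose when adjusted over the list alone (median 0.98, camera adjusted p = 2.9e-06, adjusted p = 0.59 with an estimated correlation). They included IL1B (2.76 ± 0.2, adjusted p = 0.00085), IL1A (2.73 ± 0.2, adjusted p = 0.00013) and PTGS2, which encodes cyclooxygenase 2 (4.34 ± 0.42, adjusted p = 0.0088). The PTGS2 call was lost without any 1 of the 4 libraries of 6 h (control, EV, atRAL, or atRAL plus EV; adjusted p from 0.0012 to 0.18 over the 8 fits).

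Of 30 immediate early genes 16 rose and 3 fell, or 21 and 4 when adjusted over the list alone (median 0.9, camera adjusted p = 3.7e-06, adjusted p = 0.59 with an estimated correlation). KLF4 rose by 2.72 ± 0.46 (adjusted p = 0.015), a call lost without the EV, atRAL, or atRAL plus EV library of 1 h (adjusted p from 1.3e-07 to 0.052 over the 8 fits). FOSB and FOS had larger log2 changes, 6.59 ± 1.24 and 5.51 ± 1.09, that did not pass (adjusted p = 0.067 and 0.068). FOSB stood at 425 CPM with atRAL alone and at 47.4 CPM with atRAL plus EV.

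Genes of the retinoid pathway also responded. Of 21 measured retinoic acid targets and genes of retinoid metabolism 12 rose and 2 fell, or 12 and 3 when adjusted over the list alone (median 0.52, camera adjusted p = 0.0015, adjusted p = 0.59 with an estimated correlation). CYP26B1, whose enzyme degrades retinoic acid, rose by 3.12 ± 0.32 (adjusted p = 0.0045) and the retinol receptor gene STRA6 by 2.42 ± 0.2 (adjusted p = 0.00018). NRIP1 rose by 2.15 ± 0.1 (adjusted p = 2e-05) and CRABP2, which encodes a retinoic acid binding protein, by 2.13 ± 0.15 (adjusted p = 0.00012). CYP26B1 stood at 93.2 CPM with atRAL alone and at 29 CPM with atRAL plus EV, against 7.27 and 5.05 CPM without atRAL.

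The 13 mitochondrially encoded mRNAs all fell at 6 h with atRAL, and 13 fell when adjusted over the list alone (median -0.79, camera adjusted p = 5.6e-07, adjusted p = 0.59 with an estimated correlation). COX3 fell by 1.32 ± 0.17 (adjusted p = 0.0034) and COX1 fell by 1.13 ± 0.18 (adjusted p = 0.0065). COX2, the mitochondrial subunit gene and not cyclooxygenase, fell by 1.23 ± 0.2 (adjusted p = 0.0097). ND6 fell by 1.22 ± 0.28 (adjusted p = 0.044), a call lost without any 1 of the 4 libraries of 1 h (control, EV, atRAL, or atRAL plus EV; adjusted p from 1.4e-06 to 0.088 over the 8 fits). The share of these mRNAs in all counts was 2.18% with atRAL alone and 3.77% with atRAL plus EV, against 5.42% in the control and 5.9% with EV. Of 22 nuclear genes of the respiratory chain 0 rose and 2 fell (median -0.08, camera adjusted p = 0.2; 0 and 2 adjusted over the list alone).

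Proliferation genes fell. Of 24 G1/S and DNA replication genes 14 fell and 0 rose, or 16 and 1 when adjusted over the list alone (median -0.4, camera adjusted p = 6.6e-05, adjusted p = 0.59 with an estimated correlation). Cyclin gene CCNE2 fell by 1.35 ± 0.19 (adjusted p = 0.0028), and FEN1 (-1.11 ± 0.19) and UHRF1 (-1.08 ± 0.22) fell too. Of 26 G2/M and mitosis genes 8 fell and 0 rose, with 8 adjusted over the list alone, among them KIF20A (-0.84), MKI67 (-0.66) and CDC20 (-0.62). Their median was -0.15 (camera adjusted p = 0.0015, adjusted p = 0.63 with an estimated correlation).

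Targets of YAP and TEAD, transcription factors of cell spreading and growth, fell in 9 of 20 cases and rose in 2, with 9 and 2 adjusted over the list alone (median -0.47, camera adjusted p = 0.00044, adjusted p = 0.59 with an estimated correlation). FJX1 fell by 2.01 ± 0.22 and NUAK2 had -1.9 ± 0.28, whereas CCN1 (-2.24 ± 1.03, adjusted p = 0.26) and CCN2 (-2.16 ± 0.72, adjusted p = 0.16) did not pass.

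Among the other genes that fell most were OSR1 (-3.55), CAVIN2 (-3.51), GDF6 (-2.98), PALMD (-2.84), TXNIP, whose product binds thioredoxin (-2.82), ST6GAL2 (-2.72), CYTIP (-2.65) and RAB7B (-2.56). PGBD3 (-2.53) overlaps another gene and is uncertain. Of 23 cholesterol biosynthesis genes 9 fell and 1 rose, or 9 and 2 adjusted over the list alone (median -0.3, camera adjusted p = 0.03, adjusted p = 0.76 with an estimated correlation). HSD17B7 (-1.08) fell, a call lost without the control or the atRAL library of 6 h (adjusted p from 0.00015 to 0.066 over the 8 fits), and the feedback regulator INSIG1 rose (0.91).

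Clock genes rose in 7 of 16 cases and fell in 1, or 9 and 1 adjusted over the list alone, including NFIL3 (2.52), BHLHE40 (1.95) and NR1D2 (1.27). Their median was 0.39 (camera adjusted p = 0.0015, adjusted p = 0.59 with an estimated correlation). Of 21 hypoxia and glycolysis genes 9 rose and 0 fell, with 9 adjusted over the list alone, including NDRG1 (1.88) and VEGFA (1.53). Their median was 0.11 (camera adjusted p = 0.017, adjusted p = 0.59 with an estimated correlation). Of 28 cytosolic ribosomal protein genes 2 rose, RPL3 and RPL5, and 0 fell, with 0 adjusted over the list alone (median 0.13, camera adjusted p = 0.01, adjusted p = 0.79 with an estimated correlation).

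The remaining lists did not pass camera. Of 22 endoplasmic reticulum chaperone and unfolded protein response genes 5 rose, including the sensor gene ERN1 (2.02), XBP1 (1.52) and HERPUD1 (1.44), and 7 fell, including SDF2L1 (-1.12). Of 24 apoptosis genes 8 rose and 3 fell, with PMAIP1 at 2.54 and BBC3 at 1.44. Of 24 p53 targets 6 rose and 9 fell, with GADD45A at 1.4 and FDXR at -1.17. Interferon genes fell in 7 of 22 cases and rose in 1 (camera adjusted p = 0.053), with IFIT1 at -2.16. Matrix and TGF-beta genes fell in 6 of 24 cases and rose in 2, with THBS1 at -2.27. Of 20 heat shock genes 4 rose, including HSPB8 (1.65), and 1 fell, and HSPA6 did not pass (4.99 ± 1.45, adjusted p = 0.11).

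Members that rose and fell numbered 1 and 6 of 21 for aldehyde detoxification, 3 and 5 of 21 for other antioxidant enzymes, and 5 and 2 of 18 for fatty acid and lipid droplet genes (PLIN2 at 1.83). The counts were 2 and 1 of 13 for vesicle cargo genes, 1 and 0 of 15 for complement, 2 and 0 of 6 for metallothioneins and 0 and 1 of 10 for histones. Adjusted over the list alone, they were 9 and 4 for apoptosis, 6 and 11 for p53 targets, 5 and 8 for the unfolded protein response, 1 and 9 for interferon genes, 2 and 7 for matrix genes and 3 and 1 for heat shock genes. They were 6 and 2 for the lipid list, and the same numbers as over all genes for the aldehyde, antioxidant, vesicle, complement, metallothionein and histone lists. Median and mean differed in sign for p53 targets (-0.15 and 0.09), the unfolded protein response (-0.09 and 0.07), metallothioneins (-0.07 and 0.12) and histones (-0.04 and 0.13). They did so too for the retinal pigment epithelium list (-0.16 and 0.04) and the epithelial markers (-0.19 and 0.3).

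**Figure D2:**
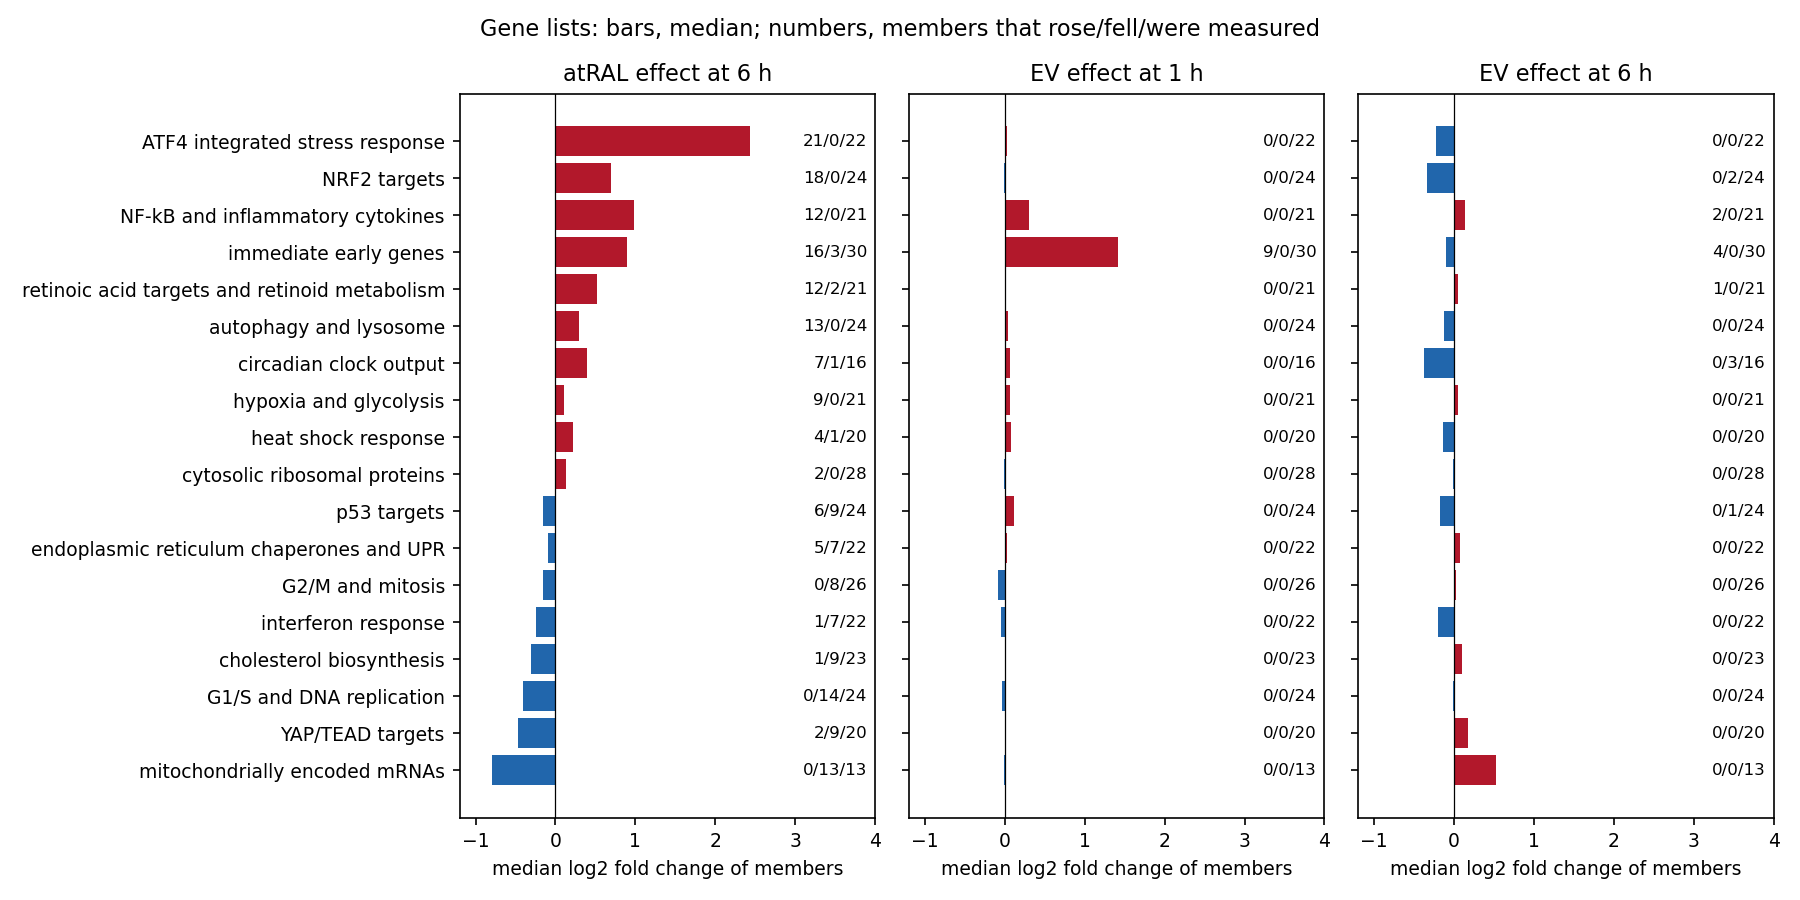
Median log2 fold change of the members of 18 gene lists for atRAL at 6 h, EV at 1 h and EV at 6 h, with the numbers of members that rose, fell and were measured beside each bar. The ATF4 list has the highest median with atRAL at 6 h (2.43), and the immediate early genes with EV at 1 h (1.42).

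For atRAL at 6 h, camera called 14 of 32 lists, 0 of them with an estimated correlation (smallest adjusted p = 0.59). Fry, a rotation test of the members' common direction, called 6, namely the ATF4, NF-kB, retinoid, aldehyde, matrix and interferon lists. DESeq2 called 4314 genes and limma-voom 5270, and edgeR's unadjusted p was under 0.05 for 7103. On counts simulated for this comparison over 17044 genes, 71.6% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes were recovered. The changed genes all had an average log2 CPM above 1, so these rates do not cover genes at lower counts. Of 200 calls 24 were false, more than the nominal share. With 200 changed genes simulated, that share need not hold for the 5140 genes called in the data. Without the EV term in the model, the calls of ATF3, PTGS2, IL1B, ND6, BHLHE40 and ANGPTL4 ended (adjusted p up to 0.21, for ANGPTL4). With the 4 libraries of 6 h alone, those of BMP4, OSGIN1, KLF4 and ND6 ended (adjusted p up to 0.1, for ND6). The ND6 call also ended with a stricter filter on low counts.

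After 1 h, 1 gene was called for atRAL. ANGPTL4, which encodes an inhibitor of lipoprotein lipase, rose by 1.00 ± 0.08 (adjusted p = 0.042), at 70.5 and 178 CPM with atRAL against 36.3 and 87 without. It rose by 1.65 ± 0.08 at 6 h (adjusted p = 2.9e-05). With readthrough models and genes under 20 counts in either library set aside, a choice made after the values were seen, the 6 genes furthest above the control with atRAL alone were LINC02035 (2.23 against 0.421 CPM), RASL11A (8.19 against 1.75), FOSB (38.5 against 11.9), CXCL8 (16.7 against 5.66), BEX4 (2.87 against 0.964) and CYP26B1 (14.9 against 5.52). Furthest below under the same limits were LUZP6 (6.59 against 32.5 CPM), FAM222A, RUSC1-AS1, ZNF239, GDNF and GYPE. Among the retinoid genes 15 of 21 lay above 0 (median 0.11, camera adjusted p = 1.7e-05, adjusted p = 0.74 with an estimated correlation). Of 30 immediate early genes 21 lay above 0 (median 0.3, camera adjusted p = 9.6e-06, adjusted p = 0.74 with an estimated correlation). Over all genes 0 members of either list were called, and 1 retinoid gene rose, and 4 immediate early genes rose and 1 fell, when adjusted over the list alone.

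The unadjusted p was under 0.05 for 323 genes at 1 h, DESeq2 called 24 genes and limma-voom 1. The ANGPTL4 call was lost in the 4 fits that each left out a library of 1 h (control, EV, atRAL, or atRAL plus EV; 0 genes each). Without the control, EV, atRAL, or atRAL plus EV library of 6 h, 49, 49, 48 and 48 genes were called.

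The difference between the 2 times was tested directly. The effect of atRAL was more positive at 6 h than at 1 h for 1360 genes and more negative for 926. CHAC1 differed by 5.67 ± 0.17 (adjusted p = 1.6e-05), CTH by 5.27 ± 0.21 (adjusted p = 6e-05), TRIB3 by 4.7 ± 0.29 (adjusted p = 0.0015), SESN2 by 4.32 ± 0.14 (adjusted p = 1.6e-05) and HMOX1 by 4.49 ± 0.39 (adjusted p = 0.0086). In the other direction stood CAVIN2 (-3.48 ± 0.26, adjusted p = 0.00057), OSR1 (-2.98 ± 0.24, adjusted p = 0.00078), PALMD (-2.86 ± 0.3, adjusted p = 0.0021), SLITRK5 (-2.51) and ADAMTS15 (-2.4). Of the 22 genes of the ATF4 list 18 were more positive at 6 h and 0 more negative, or 21 and 0 adjusted over the list alone (median 2.42, camera adjusted p = 6.4e-25, adjusted p = 0.63 with an estimated correlation). Of the 13 mitochondrial mRNAs 7 were more negative, 13 over the list alone (median -0.78, camera adjusted p = 1.2e-06, adjusted p = 0.69 with an estimated correlation).

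For this difference DESeq2 called 2126 genes and limma-voom 2230. The edgeR count of 2286 was 260, 210, 260 and 209 without the control, EV, atRAL, or atRAL plus EV library of 1 h, and 3743 and 3738 without the EV or atRAL plus EV library of 6 h. The calls of HMOX1 and PALMD were lost without any 1 library of 1 h, with adjusted p up to 0.081 and 0.066.

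**Figure D3:**
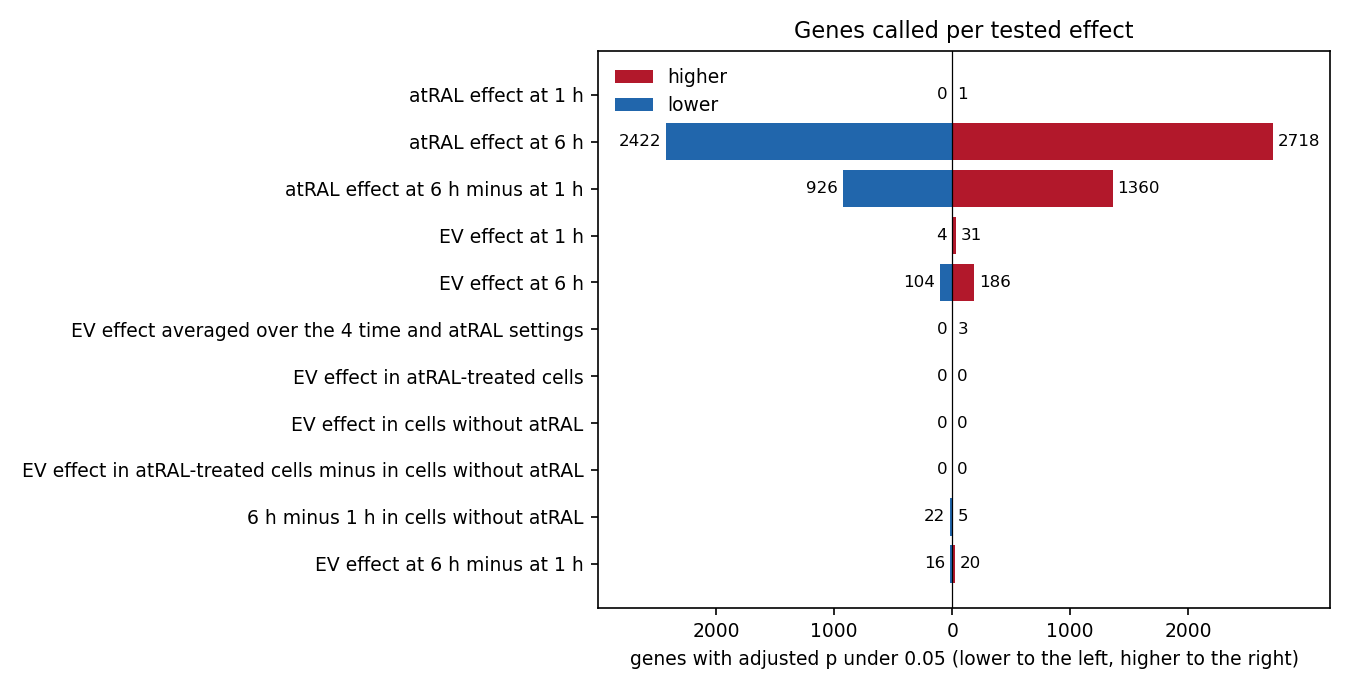
Number of genes with an adjusted p under 0.05 in edgeR for each tested effect, genes that were higher to the right and genes that were lower to the left. The atRAL effect at 6 h has 2718 and 2422 genes, the EV effect at 6 h 186 and 104, and 3 of the EV effects have 0.

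The next question is what EV do. After 1 h with EV, immediate early genes, which respond to growth factor and stress signals without new protein synthesis, were higher both with and without atRAL. EGR2 rose 17-fold (4.09 ± 0.19, adjusted p = 0.0011), JUNB by 2.17 ± 0.17 (adjusted p = 0.016) and IER2 by 1.52 ± 0.1 (adjusted p = 0.0011). ZFP36, which encodes an mRNA-destabilising protein, rose by 2.14 ± 0.2 (adjusted p = 0.045). DUSP6 rose by 1.65 ± 0.1 (adjusted p = 0.0011) and DUSP5 by 1.5 ± 0.09 (adjusted p = 0.0011), both members of this list, and SPRY4, outside it, by 1.74 ± 0.15 (adjusted p = 0.0086). Of the 30 immediate early genes 9 rose and 0 fell, 24 rose when adjusted over the list alone, and 30 of 30 lay above 0. Their median was 1.42 (camera adjusted p = 3.2e-66, adjusted p = 0.62 with an estimated correlation).

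SERPINB2, which encodes a plasminogen activator inhibitor, rose by 1.53 ± 0.12 (adjusted p = 0.0038) and the Notch target HES1 by 1.48 ± 0.16 (adjusted p = 0.035). The EGF receptor ligand gene HBEGF, named after its value was seen, rose by 1.44 ± 0.11 (adjusted p = 0.0032). EGR3 (3.85 ± 0.51, adjusted p = 0.5), FOS (3.67 ± 0.87, adjusted p = 1) and FOSB (3.56 ± 0.97, adjusted p = 1) did not pass. FOS stood at 41.3 and 48.7 CPM with EV against 2.19 and 5.32 without. Of 21 NF-kB genes 0 were called, 6 rose when adjusted over the list alone and 20 lay above 0, with PTGS2 at 2.69 ± 0.42 and CXCL8 at 1.64 ± 0.22. Their median was 0.3 (camera adjusted p = 1.9e-11, adjusted p = 0.62 with an estimated correlation). Of 24 p53 targets 0 were called and 4 rose when adjusted over the list alone (median 0.11, camera adjusted p = 0.00038, adjusted p = 0.81 with an estimated correlation).

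In all, 31 genes rose and 4 fell with EV at 1 h. POC1B-GALNT4, a readthrough model, and MIR34AHG are uncertain, and their calls ended in limma-voom and on FPKM + 1. MIR34AHG had 0 counts in both libraries with EV, at least 68.5-fold and 86.6-fold lower than the paired libraries by a floor of 3 counts per library. Over the series 34 genes had 0 counts in one library and at least 100 in another, and 11 of them were readthrough models. The unadjusted p was under 0.05 for 771 genes, DESeq2 called 107 and limma-voom 32. In the simulation of this effect 70.1%, 97% and 100% of 1.5-fold, 2-fold and 4-fold changes were recovered and 22 of 200 calls were false. The count of 35 was 2, 2, 1 and 1 without the control, EV, atRAL, or atRAL plus EV library of 1 h, and 194, 193, 192 and 191 without the same libraries of 6 h. EGR2 kept its call in all 8 of these fits (adjusted p up to 0.046), while DUSP5, DUSP6, IER2, JUNB, ZFP36, SPRY4, SERPINB2, HES1 and HBEGF lost it without any 1 library of 1 h (adjusted p up to 0.9, for HES1). POC1B-GALNT4 and MIR34AHG lost it in the same 4 fits (adjusted p up to 1 and 0.11).

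After 6 h with EV, ESM1, which encodes the proteoglycan endocan, rose 7.08-fold (2.82 ± 0.32, adjusted p = 0.048) and SERPINB2 6.76-fold (2.76 ± 0.12, adjusted p = 0.00036). PTX3, which encodes the soluble pattern receptor pentraxin 3, rose 3.99-fold (2 ± 0.08, adjusted p = 0.00012) and BMP2 3.81-fold (1.93 ± 0.14, adjusted p = 0.0025). PTX3 stood at 215 CPM with EV against 55.6 in the control. Further genes that rose were the potassium channel gene KCNK3 (2.12), METTL7B (1.84), the scaffold gene AKAP12 (1.8), BMPER (1.79) and DAW1 (1.69). KRTAP2-3 (2.54) comes from a cluster of near-identical copies and is uncertain. The cytokine genes IL1B (1.39 ± 0.19, adjusted p = 0.047) and IL6 (1.05 ± 0.14, adjusted p = 0.018) rose too, 2 of 21 in the NF-kB list and 4 adjusted over the list alone. The median of that list was 0.14 (camera adjusted p = 0.031, adjusted p = 0.79 with an estimated correlation). Taken apart, the median log2 ratio was 0.42 for EV against control (16 of 21 above 0) and -0.18 for atRAL plus EV against atRAL (10 of 21).

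Among the genes that fell, AKR1B10, an aldo-keto reductase gene with near-identical relatives, fell by 1.58 ± 0.25 (adjusted p = 0.033). BCL2L11, which encodes the pro-apoptotic protein BIM, fell by 1.26 ± 0.19 (adjusted p = 0.035), and PIK3IP1, whose product restrains PI3 kinase, fell by 1.26 ± 0.15 (adjusted p = 0.011). CXXC4 (-1.28), AZIN2 (-1.25), SAMD11 (-1.21), ASAP3 (-1.2), SLC2A12 (-1.16), REPS2 (-1.16) and KLHL24 (-1.15) fell as well. Of 24 NRF2 targets 2 fell, AKR1B10 and AKR1C3 (3 adjusted over the list alone), and 2 of 24 lay above 0 (median -0.34, camera adjusted p = 9.6e-06, adjusted p = 0.79 with an estimated correlation). Clock genes fell in 3 of 16 cases, 6 adjusted over the list alone, including TEF (-0.7) and NR1D2 (-0.66). Their median was -0.38 (camera adjusted p = 8e-04, adjusted p = 0.79 with an estimated correlation).

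The mitochondrial mRNAs stood higher with EV at 6 h, where 0 of 13 passed over all genes, 12 passed adjusted over the list alone, and 13 lay above 0. Their median was 0.53 (camera adjusted p = 1.9e-07, adjusted p = 0.79 with an estimated correlation). Of 22 ATF4 genes 0 passed over all genes, 2 fell when adjusted over the list alone and 3 lay above 0 (median -0.22, camera adjusted p = 0.00023, adjusted p = 0.79 with an estimated correlation). The metallothionein genes MT2A (0.47) and MT1E (0.41), near-identical and uncertain, rose, 2 of 6 and 3 over the list alone (median 0.31, camera adjusted p = 0.013, adjusted p = 0.79 with an estimated correlation). CD9, which encodes a tetraspanin used as a vesicle marker, rose by 0.53 ± 0.08 (adjusted p = 0.031), the only call among 13 vesicle cargo genes. Taken apart, EV against control and atRAL plus EV against atRAL had medians of 0.19 and 0.82 for mitochondrial mRNAs, -0.08 and -0.56 for NRF2 targets, -0.14 and -0.62 for clock genes, -0.03 and -0.38 for ATF4 genes and 0.3 and 0.37 for metallothioneins. Except for the last, these list medians come mostly from the pair with atRAL.

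In all, 186 genes rose and 104 fell with EV at 6 h. The unadjusted p was under 0.05 for 3175 genes, DESeq2 called 708 and limma-voom 372. In the simulation 71.6%, 91% and 100% of 1.5-fold, 2-fold and 4-fold changes were recovered and 22 of 197 calls were false. The edgeR count of 290 was 24, 20, 20 and 20 without the control, EV, atRAL, or atRAL plus EV library of 1 h and 1918 and 1913 without the control or EV library of 6 h. It was 49 with no filter on low counts, 544 with a stricter one and 54 with the 4 libraries of 6 h alone. SERPINB2, PTX3, BMP2, KCNK3, AKAP12, KRTAP2-3 and KLHL24 kept their calls in all 8 fits that left out a library. The other genes named so far as called for EV at 6 h lost theirs without each of the 4 libraries of 1 h (adjusted p up to 0.2, for ESM1). AKR1B10, AKR1C3, TEF and MT1E lost it also without the atRAL or atRAL plus EV library of 6 h, AZIN2 without the atRAL library of 6 h, and REPS2 without the control or EV library of 6 h. On log2(FPKM + 1) 25 of 37 calls named for EV at 6 h ended, BMP2 (adjusted p = 0.063), KLHL24 (0.079), BMPER, SLC2A12 and IL6 among them. With no filter on low counts 20 of 37 ended, and with the 4 libraries of 6 h alone 19. AKR1B10, CXXC4, BCL2L11, AZIN2, REPS2, AKR1C3, TEF, NR1D2, MT2A, MT1E, CD9, SAMD11, ASAP3 and IL6 ended in all 3 of these settings, and ESM1 in each but the fit with no filter.

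Of the genes that rose with EV, 7 were shared between 1 h and 6 h, against 0.34 by independent draws. The shared genes were ANGPTL4, DUSP5, DUSP6, HBEGF, MAFF, SERPINB2 and the uncertain POC1B-GALNT4. The 2 effects share no library, but they come from the same fit with a common spread per gene. A gene with a small spread is easier to call at both times, so 0.34 is not a chance rate. The test of the difference between the times, added after the data were examined, called 36 genes. The EV effect was more positive at 6 h for 20 of them, including KCNK3 (2.05), PTX3 (1.91) and BMP2 (1.84), and more negative for 16, including EGR2 (-4.36), JUNB (-2.68), IER3 (-1.48) and IER2 (-1.29). DESeq2 called 211 genes for it, 75 more positive and 136 more negative, and limma-voom 32, 14 and 18, so the majority depends on the tool. EdgeR's unadjusted p was under 0.05 for 2068.

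The series title is about a therapeutic effect of EV, and their effect in cells that received atRAL is the central comparison. With atRAL present for 6 h, the library with EV stood furthest above the one without for ESM1 (96.2 against 9.08 CPM), DKK1, a WNT inhibitor gene (16.9 against 2.12), SERPINB2 (120 against 16.3), MIR17HG (3.39 against 0.469), CCN1 (323 against 52) and the tissue factor gene F3 (395 against 69). It stood furthest below for HSPA6 (0.549 against 28.6 CPM), FOS (8.14 against 111), DISC1 (0.339 against 4.7), FOSB (47.4 against 425), KRTAP5-AS1 (0.63 against 5.48) and RRAD (3.02 against 20.9). DISC1 is uncertain, since the readthrough model TSNAX-DISC1 moved the other way, with 201 counts with EV against 11 without. From further down the order, BMP2 (65.8 against 15.1 CPM) was higher and ATF3 (26.8 against 165) lower, both picked after their values were seen. HSPA1A (92.1 against 505 CPM) and HSPA1B (117 against 644), picked in the same way, were lower, but are near-identical copies and uncertain. CXCL8 (217 against 116 CPM), IL1B (227 against 104) and PTGS2 (142 against 89.8) were higher with EV, named after their values were seen.

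At 1 h with atRAL, EGR2 stood at 38.5 CPM with EV against 3 without, EGR3 at 367 against 30.9, FOS at 48.7 against 5.32, FOSB at 347 against 38.5, NR4A3 at 17 against 2.28 and ATF3 at 31.7 against 5.41, the 6 furthest above. Furthest below stood PP7080 (0.385 against 8.74 CPM), FAM71F2 (1.17 against 3.2), SUOX (12 against 27.3), STBD1 (7.17 against 15.7), TESMIN and TMEFF1. STBD1 is uncertain, since the readthrough model FAM47E-STBD1 moved the other way, with 610 counts with EV against 23 without. PP7080 is uncertain too, since at 6 h it had 422 counts with atRAL plus EV against 0 with atRAL alone. The genes named for these pairs at both times were taken with readthrough models left out and at least 20 counts in both libraries, a choice made after the values were seen. By the rule fixed before, 51 of the 72 genes named over 6 such pairs were readthrough models or at 0 in one library and are uncertain.

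Genes at least 2-fold apart numbered 73 higher and 16 lower with EV at 1 h in atRAL-treated cells, and 159 higher and 207 lower at 6 h. For comparison, atRAL against control gave 22 higher and 18 lower at 1 h and 714 and 473 at 6 h, and EV against control 65 and 29 at 1 h and 83 and 52 at 6 h. These are counts by size alone, between 1 library and 1. With a minimum of 20 counts in place of 100, the majority turned for atRAL against control at 1 h (111 higher and 140 lower) and for EV against control at 1 h (175 and 180) and at 6 h (208 and 233).

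By gene list, the median log2 ratio of atRAL plus EV against atRAL at 6 h was 0.82 for the mitochondrial mRNAs (13 of 13 above 0), 0.46 for YAP targets (18 of 20) and 0.31 for cholesterol genes (19 of 23). Each lay at percentile 100 among 10000 random lists matched on expression. It was -0.62 for clock genes (2 of 16 above 0), -0.56 for NRF2 targets (2 of 24), -0.41 for immediate early genes (9 of 30), -0.38 for ATF4 genes (0 of 22) and -0.35 for heat shock genes (4 of 20), at percentile 0 in each case. For the NF-kB list it was -0.18 (10 of 21, percentile 2.01), and for apoptosis genes -0.02 (12 of 24, percentile 39.55). At 1 h the same medians were -0.1 for the mitochondrial mRNAs (0 of 13 above 0, percentile 0), 0.06 for YAP targets (14 of 20, percentile 98.93), 0.06 for cholesterol genes (17 of 23, percentile 98.7), 0.01 for clock genes (10 of 16, percentile 64.32) and 0 for NRF2 targets (12 of 24, percentile 48). They were 1.3 for immediate early genes (30 of 30, percentile 100), 0.08 for ATF4 genes (17 of 22, percentile 99.95), 0.05 for heat shock genes (14 of 20, percentile 98.19), 0.32 for the NF-kB list (20 of 21, percentile 100) and 0.04 for apoptosis genes (15 of 24, percentile 89.7). Of these 10 medians, those of the mitochondrial, immediate early, ATF4, heat shock, NF-kB, clock and apoptosis lists had opposite signs at the 2 times. The random lists lack the co-regulation of a gene list, and each ratio rests on 1 library against 1. The percentiles are therefore ranks and give no chance rate, and a median of -0.1 (mitochondrial mRNAs at 1 h) was enough for percentile 0.

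A test of EV in atRAL-treated cells, with the 2 times as repeats, called 0 genes in edgeR (smallest adjusted p = 0.404). The unadjusted p was under 0.05 for 531 genes, DESeq2 called 14 and limma-voom 0. Camera called 13 of 32 lists, including YAP targets (median 0.29, adjusted p = 2.5e-07), immediate early genes (0.47, adjusted p = 2.4e-07), mitochondrial mRNAs (0.38, adjusted p = 7.2e-07) and NRF2 targets (-0.28, adjusted p = 4.6e-06). All 4 had adjusted p = 0.68 with an estimated correlation, and 4 immediate early genes rose when adjusted over the list alone against 0 in the other 3 lists. These medians average the times, and for the mitochondrial mRNAs and immediate early genes the 2 pairs had opposite signs. The simulation of this test recovered 43.3%, 79.1% and 98.5% of 1.5-fold, 2-fold and 4-fold changes, with 27 of 174 calls false. It gave each changed gene the same fold change at both times. An EV effect at 1 time only adds to the spread of this model, so the rates do not cover such effects. The edgeR count was 542 and 547 without the atRAL or atRAL plus EV library of 1 h and 18 and 19 without those of 6 h.

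The response to atRAL was then compared between cells with and without EV at 6 h, over the genes called for atRAL. Among the 2718 that rose, the median log2 response was 0.66 without EV and 0.512 with EV, and it was smaller with EV for 2030 genes (74.7%). The median difference was -0.142 (95% bootstrap interval over genes -0.152 to -0.13, percentile 0 among matched lists). Among the 2422 that fell the median was -0.597 without and -0.467 with EV, a difference of 0.129 (0.118 to 0.143, percentile 100), smaller in size in 1715 (70.8%). Genes are not independent replicates, each response rests on 1 library against 1, and the percentiles are ranks and not chance rates. The call itself counts the difference between the responses with and without EV as spread, so genes with a large difference tend to fail it. FOSB, FOS, HSPA6 and CCN1 were among the genes not called. The medians and shares therefore describe the called genes only.

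**Figure D4:**
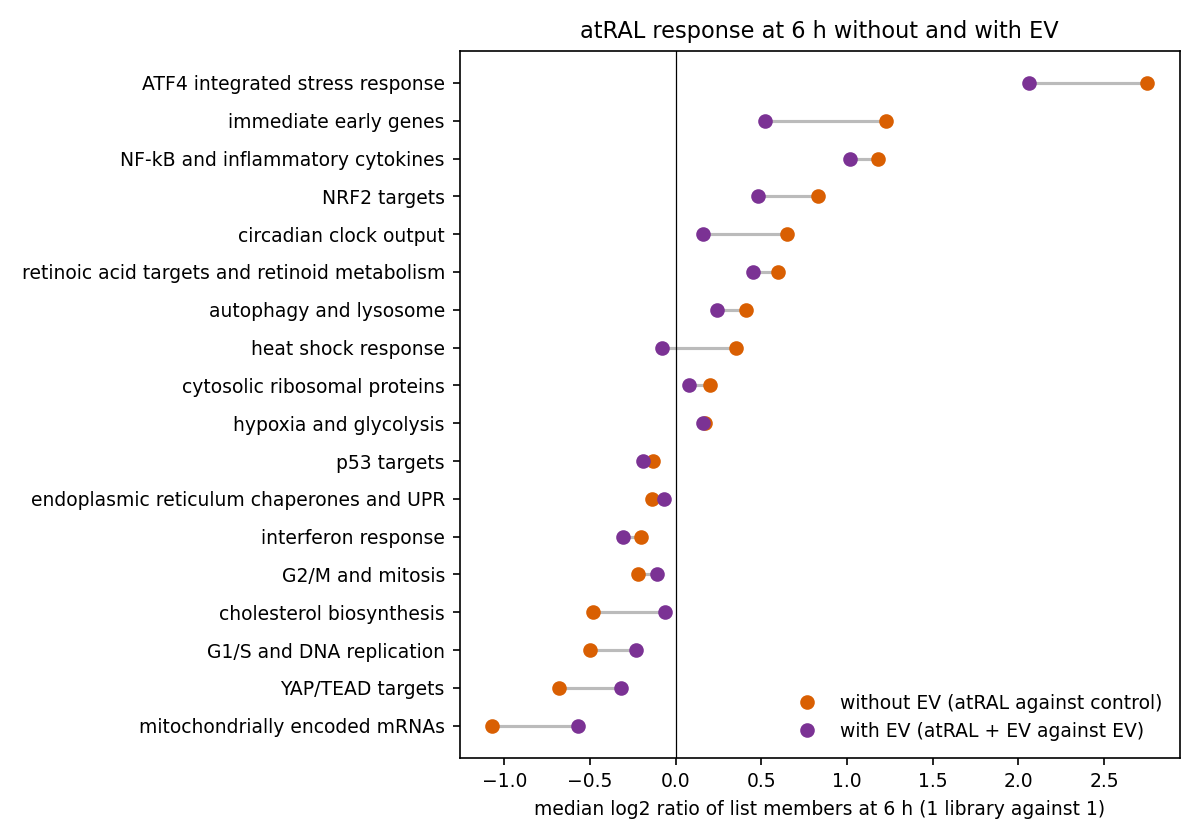
Median log2 ratio of the members of 18 gene lists for atRAL against control (without EV) and for atRAL plus EV against EV (with EV) at 6 h, each 1 library against 1. The median of the ATF4 list is 2.75 without and 2.06 with EV, and that of the mitochondrial mRNAs -1.07 and -0.57.

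The list medians without and with EV were 2.75 and 2.06 for ATF4 genes, 0.83 and 0.48 for NRF2 targets, 1.23 and 0.52 for immediate early genes and 1.18 and 1.02 for NF-kB genes. They were 0.6 and 0.45 for retinoid genes and 0.35 and -0.08 for heat shock genes. Among lists with negative medians they were -1.07 and -0.57 for mitochondrial mRNAs, -0.68 and -0.32 for YAP targets, -0.5 and -0.23 for G1/S genes and -0.48 and -0.06 for cholesterol genes. Across all 17044 genes the responses with and without EV correlated at r = 0.586 (Spearman 0.635) at 6 h and r = 0.006 (Spearman -0.045) at 1 h, over genes that are not independent.

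The test of the EV effect in atRAL-treated cells minus that without atRAL, with the times as repeats, called 0 genes in edgeR. The unadjusted p was under 0.05 for 194 genes, and DESeq2 and limma-voom called 0. Camera called 15 lists, with YAP targets at a median of 0.3 (adjusted p = 7.1e-09), G1/S genes at 0.21 (adjusted p = 1.4e-08), cholesterol genes at 0.17 (adjusted p = 6.6e-06) and heat shock genes at -0.18 (adjusted p = 6.4e-05). All 4 had adjusted p = 0.56 with an estimated correlation and 0 called members, also when adjusted over the list alone. The edgeR count was 126 and 127 without the atRAL or atRAL plus EV library of 1 h and 9 and 8 without those of 6 h.

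Averaged over the 4 settings of time and atRAL, 4 libraries against 4, EV raised HBEGF (1.28 ± 0.1, adjusted p = 0.012), ANGPTL4 (1.14 ± 0.08, adjusted p = 0.0095) and IL6 (0.99 ± 0.1, adjusted p = 0.047), each higher with EV in 4 of 4 pairs. The unadjusted p was under 0.05 for 1207 genes, DESeq2 called 70 genes and limma-voom 4. The simulation, with changes equal in all 4 settings, recovered 85.1%, 94% and 100% of 1.5-fold, 2-fold and 4-fold changes, with 26 of 212 calls false. The count fell to 0 without the control or EV library of 1 h or of 6 h, and was 19 and 20 without the atRAL or atRAL plus EV library of 6 h. Without the atRAL or atRAL plus EV library of 1 h it was 3, but HBEGF and IL6 were not among the calls. On log2(FPKM + 1) 0 of the 3 kept their call (adjusted p up to 0.13).

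In cells without atRAL and over both times, immediate early genes stood higher with EV, with 30 of 30 above 0 and a median of 0.81 (camera adjusted p = 7.9e-15, adjusted p = 0.78 with an estimated correlation; 0 called and 2 adjusted over the list alone). The median log2 ratio was 1.49 at 1 h (29 of 30 above 0) and 0.12 at 6 h (20 of 30), so the average rests mostly on 1 h. Over all genes edgeR called 0 for this effect, the unadjusted p was under 0.05 for 396, DESeq2 called 19 and limma-voom 0. The edgeR count was 30 and 30 without the atRAL or atRAL plus EV library of 1 h and 17 and 14 without those of 6 h.

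Cultures without atRAL also changed between 1 h and 6 h, which sets the background for the time comparison. DIO2, which encodes the deiodinase that activates thyroid hormone, rose by 2.38 ± 0.24 (adjusted p = 0.027), CLK4 by 1.5, RBM14 by 1.2, the eye transcription factor gene OTX2 by 1.12 and the chaperone gene HSPA8 by 0.99. RAPGEF4 fell by 3.03 ± 0.33 (adjusted p = 0.027). PPFIA4 (-2.21), CHAC1 (-1.91), MAFF (-1.87), NDRG1 (-1.55), GADD45B (-1.53), HBEGF (-1.48), PLAU (-1.38), VLDLR (-1.25) and PDK1 (-1.25) fell too. Of 21 hypoxia and glycolysis genes 5 fell and 0 rose, 10 adjusted over the list alone (median -0.32, camera adjusted p = 7e-12, adjusted p = 0.76 with an estimated correlation). Of 30 immediate early genes 1 fell, 3 over the list alone (median -1.25, camera adjusted p = 5.6e-12, adjusted p = 0.91 with an estimated correlation).

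In all, 5 genes rose and 22 fell with time (unadjusted p under 0.05 for 2733, DESeq2 510, limma-voom 29). The edgeR count was 0 without the control or EV library of either time, 1064 and 1068 without the atRAL or atRAL plus EV library of 1 h and 781 and 765 without those of 6 h. It was 0 with no filter on low counts and 0 on log2(FPKM + 1), so all 15 calls named above ended in both settings.

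Markers of other cell types were summed per library. Markers of mesenchymal stromal cells, the donor type of the EV, summed to 1530, 1580, 1600 and 1530 CPM at 1 h in control, EV, atRAL, and atRAL plus EV, and to 1480, 1460, 1090 and 1210 at 6 h. Of these 19 markers 10 stood above 1 CPM in a control, and NT5E made 631 to 1040 CPM of the sums and THY1 277 to 382. With atRAL at 6 h 4 of 13 measured members fell, including PDGFRA (-1.72) and PRRX1 (-1.29), and 1 rose (4 and 1 adjusted over the list alone). With EV at 6 h PDGFRB fell by 0.89 ± 0.08 (adjusted p = 0.0044), a call lost without the EV, atRAL, or atRAL plus EV library of 1 h (adjusted p up to 0.052). NES rose by 0.61 ± 0.1 (adjusted p = 0.04), a call lost without any 1 library of 1 h or without the atRAL or atRAL plus EV library of 6 h (adjusted p up to 0.18), and 2 rose and 1 fell adjusted over the list alone. Leukocyte markers summed to 89.8 to 97.4 CPM, of which CD68, also a lysosomal protein gene, made 89 to 96.6. Keratinised and simple epithelial markers summed to 28.4 to 37.4 CPM, of which KRT7 made 19.5 to 30.9, and erythroid and platelet markers to 0 in all 8 libraries. Retinal pigment epithelium markers summed to 1260 to 1510 CPM, of which KRT8 made 615 to 798 and KRT18 351 to 517. TTR, TYR, DCT, CRX and TRPM1 stood at 0 in all 8 libraries and RPE65 at 0.126 CPM at most. Of 12 measured retinal pigment epithelium genes 4 rose and 1, OTX2 (-0.8), fell with atRAL at 6 h (4 and 1 over the list alone), and 0 of 5 leukocyte and 1 of 5 epithelial genes was called (0 and 1 over the list alone). Of the 4 that rose, BEST1 and LRAT stood at 0.828 and 0.477 CPM in the control of 6 h.

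The design text of the series names k-means clustering, which was repeated here with 4 clusters of the 2000 most variable genes. A cluster of 692 genes was highest with atRAL at 6 h (mean centred log2 CPM 1.41 without and 1.15 with EV) and held 17 of 22 ATF4 genes against 0.89 by chance. A cluster of 616 genes was lowest there (-1.23 and -0.92) and held 8 of 20 YAP targets against 0.72. A cluster of 385 genes was lowest at 6 h without atRAL (-0.76 in the control and -0.97 with EV). At 6 h this cluster stood at 0.43 with atRAL alone and at -0.43 with atRAL plus EV. It held 18 of 30 immediate early genes against 0.68, EGR1, EGR2 and FOS among them. A cluster of 307 genes was set by a low value in the atRAL library of 1 h (-1.79), the shallowest of the 8.

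Time was the leading contrast of all 4 clusters, which held 100% of the genes, but with 3 clusters 29% and with 6 clusters 20.8% of the genes lay in clusters led by atRAL. The clusters of 692 and 616 genes stood furthest apart from the rest in the libraries with atRAL at 6 h, so their lead by time takes in the atRAL response at 6 h. Of the variance over 17044 genes, time held 28.1%, atRAL 19.1%, their interaction 16.5%, EV 10.8%, time with EV 10.8%, atRAL with EV 7.2% and the 3-way term 7.6%. The share of time likewise averages over cells with and without atRAL.

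In the deposited table, genes are identified by NCBI gene number and symbol. On GRCh38, CHAC1 (gene 79094) lies on chromosome 15 from 40953471 to 40956512, and HMOX1 (3162) on chromosome 22 from 35381096 to 35394207. EGR2 (1959) lies on chromosome 10 from 62811996 to 62819167 and ANGPTL4 (51129) on chromosome 19 from 8364155 to 8374370, and all 4 are protein-coding genes.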

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

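The tests of mixing, of differences between dishes, of handling and of scaling, the swaps of EV within pairs, and the difference of the EV effect between the times, were chosen only after the results were seen. The effect of atRAL differed between 6 h and 1 h for 2286 genes, by a test of the difference itself. The effect of EV differed between the times for 36 genes, by the same kind of test. The first count was 260, 210, 260 and 209 without the control, EV, atRAL, or atRAL plus EV library of 1 h, and 3743 and 3738 without the EV or atRAL plus EV library of 6 h. With 1 library in each group, no test for an outlying library within a group was possible.

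With atRAL for 6 h, cells that also received EV showed a smaller response, with a median difference of -0.142 over the called genes that rose. That call disfavours genes whose responses with and without EV differ widely. Library depth is argued against, since the difference was -0.143 (95% interval -0.155 to -0.134) with the libraries of 6 h thinned to the smallest total. For admixture of RNA from cells that did not respond, or a common loss of exposure to atRAL, the linear response with EV was 65.1% of that without for 675 genes that rose at least 2-fold and 79.1% for 426 that fell, and the difference of -0.14 (-0.184 to -0.091) straddles the bound of 0.1 in size set for it. A single dilution would give 1 ratio for all genes, but the middle 50% of genes ran from 48.8% to 87.9% for those that rose and list medians from 47.8% (NRF2 targets) to 96% (retinoid genes), a spread that 1 library per condition cannot part from differences between dishes, so neither explanation is excluded. That EV weaken the response inside the cells may be so, and it remains a hypothesis beside those.

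At 1 h, immediate early genes stood higher with EV. Handling shared by every treated dish as the whole cause is argued against, since the median log2 ratio was 0.31 with atRAL alone and 1.49 with EV alone, a quotient of 0.204 (0.076 to 0.332), and 28 of 30 genes had the larger ratio with EV. A shared part is not excluded, since 22 of 30 genes lay above 0 with atRAL alone. Each ratio rests on 1 library against 1, so differences between dishes stay open here too. A signal of the vesicles themselves is a candidate explanation, and soluble factors or other contents of the EV preparation, for which the series has no mock preparation, were not tested.

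At 6 h with atRAL, the mitochondrially encoded mRNAs fell, with a median of -0.79 (-1.13 to -0.75). Loss of short transcripts is argued against over the lengths covered. Taken as 1 set, 484 nuclear protein-coding genes of the nearest effective length had a median of -0.11 (-0.13 to -0.08). Their effective lengths ran from 347 to 2094 and those of the mitochondrial mRNAs from 238 to 2080, so the shortest mitochondrial mRNAs were not matched. Scaling of the libraries as the whole cause is argued against too, since a scaling factor moves all genes of a library alike and the 2 medians differed by -0.68 (-1.03 to -0.63), though all of these are relative abundances. A lower output or stability of mitochondrial transcripts may explain it, a hypothesis that arose from these data and was not tested, and the difference between dishes stays open here too.

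For EV averaged over the 4 settings of time and atRAL, 3 genes were called with the real split of the 8 libraries. Of 35 splits into 4 and 4, 32 could be fitted, and 5 of these, the real one included, called as many genes, and the highest other split called 653 genes. That split, with the control and EV libraries of 1 h and the control and atRAL libraries of 6 h against the rest, amounts to the EV effect at 6 h alone, because the model already allows for each setting of time and atRAL. The other splits with as many genes likewise amount to the EV effect at a single time, so these splits give no chance rate. With EV swapped within the 4 pairs there are 8 splits, too few for a share under 0.125, where the real one called 3 genes and the highest other 0.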

How the results depend on the processing

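Leaving out mitochondrial mRNAs and ribosomal RNA genes, leaving out readthrough genes, and the EV effect at 6 h minus that at 1 h were chosen only after the data were seen. Of 261 alternative values for 39 results, 122 kept the call or stayed within the spread or 1.5 times the count, 139 moved and 0 reversed. Only the difference of the atRAL response with and without EV could be scored as reversed. The 0 therefore says nothing about the counts, shares and lists, and the majority of higher or lower genes did turn in some settings. For 171 named gene results, 2262 of 2702 alternative values kept direction and call, 440 kept direction but lost the call and 0 reversed. In 91 of the 171 the call was kept in all settings run, and leaving out a library lost it in 293 of 1256 values. DESeq2 lost it in 0 of 171, limma-voom in 5 of 171, RLE scaling in 1 of 157, a minimum count of 50 in 4 of 157, no filter in 37 of 157, log2(FPKM + 1) in 47 of 157, log2(FPKM + 0.1) in 23 of 157, no EV term in 7 of 73, and the 4 libraries of a time alone in 23 of 125. Without mitochondrial mRNAs and ribosomal RNA genes it was lost in 0 of 121.

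Where a library was left out, an arm holds 1 library, which is assumed to vary like the other groups. Counts of called genes then ran from 0 to 49 for atRAL at 1 h, 3556 to 5427 for atRAL at 6 h, 209 to 3743 for their difference, 1 to 194 for EV at 1 h and 20 to 1918 for EV at 6 h. They ran from 0 to 20 for EV averaged, 0 to 547 for EV with atRAL, 0 to 30 for EV without atRAL, 0 to 127 for the difference of these and 0 to 1068 for 6 h against 1 h. Fewer libraries leave 1 or 2 residual degrees of freedom. In the model with both treatments within each time, a time that loses a library has none left, so the spread comes from the other time alone. For EV at 1 h the counts were 2, 2, 1 and 1 without a library of 1 h and 194, 193, 192 and 191 without one of 6 h, so they follow the time and hardly the library, and do not check a single one. For EV at 6 h they were 1918 and 1913 without the control or EV library of 6 h and 307 and 288 without the atRAL or atRAL plus EV library of 6 h. No paired analysis was possible because each condition has 1 library, so the groups share fewer than 2 replicate numbers, and the only pairing used is that of the layout, by time and by EV or atRAL.

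For atRAL at 1 h the count of 1 was 4 with RLE scaling, 0 with no filter, 5 with a minimum count of 50, 24 with DESeq2, 0 with log2(FPKM + 1), 0 with log2(FPKM + 0.1), 0 with no EV term, 27 with the 4 libraries alone and 4 without mitochondrial mRNAs and ribosomal RNA genes. For the difference of the atRAL effect between the times, 2286 was 1342 with no filter, 1224 with log2(FPKM + 1) and 1410 with log2(FPKM + 0.1). For EV at 1 h, 35 was 107 with DESeq2 and 134 with the 4 libraries alone. For EV at 6 h, 290 was 49 with no filter, 544 with a minimum count of 50, 708 with DESeq2, 34 with log2(FPKM + 1), 65 with log2(FPKM + 0.1) and 54 with the 4 libraries alone. For EV averaged, 3 was 70 with DESeq2 and 0 with log2(FPKM + 1). With DESeq2 the count was 14 for EV with atRAL, 19 for EV without atRAL, 510 for 6 h against 1 h (27 in edgeR) and 211 for the difference of the EV effect between the times (36 in edgeR). For 6 h against 1 h it was 0 with no filter and 0 with log2(FPKM + 1), and with log2(FPKM + 0.1) it was 20, 50% of them higher against 18.5%. No filter tests more genes, and for the other settings the cause was not tested.

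Genes at least 2-fold apart between single libraries numbered 40, 1187, 94, 135, 89 and 366 for atRAL at 1 h and 6 h, EV at 1 h and 6 h, and atRAL plus EV against atRAL at 1 h and 6 h. With a minimum of 20 counts, which admits more genes, they numbered 251, 1873, 355, 441, 352 and 829, and the share of higher genes was under 50% for the first (44.2% against 55%), the EV pair of 1 h (49.3% against 69.1%) and that of 6 h (47.2% against 61.5%). With FPKM + 1, which shrinks ratios of low values, they numbered 15, 620, 54, 33, 51 and 125. Without readthrough genes the first was 25.

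Shares of variance for time, atRAL, EV, time with atRAL, time with EV, atRAL with EV and the 3-way term were 25.8%, 18%, 11.5%, 15.6%, 11.6%, 8.6% and 8.9% with a prior count of 0.5. With a minimum count of 50 they were 32.7%, 21.3%, 9.3%, 18.5%, 8.8%, 4.4% and 4.9%. The share of clustered genes led by time, 100% with 4 clusters, was 71% with 3 clusters, 67.8% with 6, 78% with 1000 genes and 75.2% with a prior count of 4. The share led by atRAL, 0% with 4 clusters, was 29%, 20.8%, 22% and 24.8% in the same order, and that led by EV was 11.4% with 6 clusters. The smaller response of fallen genes with EV was 0.147 with the genes called by DESeq2 against 0.129. The cause of these moves was not tested.

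Lists called by camera numbered 9, 14, 13, 7, 11, 10, 13, 10, 15 and 8 for atRAL at 1 h, at 6 h and their difference, EV at 1 h, at 6 h, averaged, with atRAL, without atRAL and their difference, and 6 h against 1 h. With an estimated correlation the count was 0 for each of the 10. With fry it was 6 for atRAL at 6 h and 0 for each of the other 9. With 2 or 3 residual degrees of freedom the correlation is estimated from few values, and a list that passes only with the preset one is an observation about its members in these libraries.

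Depth limits the genes at low counts. With 45566237 to 71822269 counts per library, 3 counts correspond to 0.042 to 0.066 CPM, and a gene below that in a library was not detectable at this depth.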

Other observations

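The difference of the EV effect between the times was chosen only after the results were seen. Replication-dependent histone genes, whose polyadenylated mRNAs are a small part of all histone mRNA, stood lower with EV at 6 h in cells that received atRAL. There 0 of 10 stood above 0 for atRAL plus EV against atRAL (median log2 ratio -0.69, percentile 0.4 among 10000 matched lists). Their median response to atRAL was 0.5 without and -0.41 with EV. For EV against control at 6 h, 4 of 10 stood above 0 (median -0.2, percentile 19.24). Over both EV pairs at 6 h, 0 of 10 were above 0 and 0 were called (0 rose and 1 fell adjusted over the list alone; median -0.35, camera adjusted p = 0.035, adjusted p = 0.79 with an estimated correlation).

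Further lists were compared in atRAL-treated cells at 6 h, with EV against without. The median log2 ratio was -0.24 for p53 targets (percentile 0.02), -0.17 for autophagy and lysosome genes (0.04), -0.28 for interferon genes (0.5) and -0.34 for retinal pigment epithelium genes (0.49). It was 0.37 for metallothioneins (99.37). For EV against control at 6 h the medians in the same order were -0.13 (percentile 0.05), -0.09 (0.01), -0.07 (19.25), -0.18 (1.2) and 0.3 (99.89). These percentiles, like those of the histone genes, are ranks between single libraries and give no chance rate. With EV at 6 h the p53 target TP53INP1 fell by 0.71 ± 0.09 (adjusted p = 0.016), the only p53 target called (0 rose and 4 fell adjusted over the list alone; median -0.18, camera adjusted p = 0.0033, adjusted p = 0.79 with an estimated correlation). That call was lost without any 1 of the 4 libraries of 1 h (control, EV, atRAL, or atRAL plus EV), with adjusted p up to 0.11.

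Between 1 h and 6 h without atRAL, ATF4 genes stood lower (0 rose and 3 fell, 1 and 9 adjusted over the list alone; median -0.47, camera adjusted p = 8e-07, adjusted p = 0.93 with an estimated correlation). YAP targets did too (1 fell, 9 adjusted over the list alone; median -0.39, camera adjusted p = 4.7e-08, adjusted p = 0.91 with an estimated correlation). Heat shock genes stood higher (1 rose, 5 adjusted over the list alone; median 0.23, camera adjusted p = 1.6e-05, adjusted p = 0.91 with an estimated correlation). The calls of this comparison were 0 without the control or EV library of either time.

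For the EV effect at 6 h minus that at 1 h, 5 of 30 immediate early genes were more negative (1 more positive and 21 more negative adjusted over the list alone; median -1.38, camera adjusted p = 1.7e-26, adjusted p = 0.72 with an estimated correlation). The mitochondrial mRNAs stood above 0 in 13 of 13 cases (median 0.53, camera adjusted p = 1.3e-06, adjusted p = 0.72 with an estimated correlation). Their median log2 ratios at 1 h and 6 h were 0.08 and 0.19 without atRAL and -0.1 and 0.82 with it.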
